A study of Homo sapiens with 2 samples.

How the data were processed

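RNA was measured in 2 libraries from A549 cells, 1 infected with lentivirus for a control hairpin (shNC) and 1 with lentivirus for a hairpin against DEPDC1B (shDEPDC1B), with 5 µg/mL polybrene and harvest on day 2. Per the labels' protocols, total RNA was made into cDNA libraries and sequenced on MGI instruments. The groups were taken from the treatment label of each sample. Whether the RNA was selected for poly(A) or depleted of ribosomal RNA, whether strand was kept and what the hairpin sequences were is not given in the sources used here.

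The deposited table holds estimated counts per gene symbol, which per the submitters' processing notes come from Bowtie2 and RSEM on hg38. Versions and the gene annotation are not given in the sources used here. The deposited estimated counts are not scaled for depth and were rounded to whole numbers here, which gave 18647290 counts in shNC and 18862371 in shDEPDC1B over 39720 symbols. RSEM shares reads that match several genes or transcripts between them by a model, so genes with near copies, read-through genes and overlapping genes carry an error that the counting intervals do not hold. For 699 genes the values were not whole hundredths (tolerance 0.001 hundredths), and for 684 of these they became so when multiplied by a whole number from 2 to 8, as a mean over gene copies would. Of the genes named here these are B2M, CRIM1, TJP1, RPS9, ACACA, CHORDC1, FBL and PCK2, whose counts and intervals are uncertain. All such genes include 67 of the 93 assessed genes on chromosome 6 between 28 and 34 Mb. A symbol that a spreadsheet had turned into a date was kept as it stood.

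Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.03 for shNC and 0.967 for shDEPDC1B). With 1 library per group edgeR's tests could not be run and no p-value was computed. The ratio of scaled counts was given with an exact Clopper-Pearson 95% interval of the share of a gene's counts that fell in shDEPDC1B. Reads carry no molecular identifiers, so intervals and floors cover counting error only. A count of 0 was set to a floor of 3 counts and the ratio given as a bound. Genes were assessed at 30 counts or more in the higher library (13850 genes), and counted as higher or lower at a ratio of at least 2 with an interval that excludes equality. Directions are always those of shDEPDC1B relative to shNC, and unlabelled values beside genes and lists are log2 ratios.

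For each of 38 gene lists the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was called outside when it fell beyond the central 95%, and lists with fewer than 5 assessed genes got no percentile. The percentile describes these 2 libraries. Members were counted as higher or lower at 1.5-fold with an interval that excludes equality. A ratio above or below 1 gives the sign alone, with no such rule. Gene coordinates are from GENCODE 29 (GRCh38). Transcript length and GC content are those of the longest protein-coding transcript of each gene there, or of its longest transcript if it has no coding one, and 94.4% of assessed genes had them. Words of 7 bases were searched in annotated 3' untranslated regions of 12105 protein-coding genes after transcript and region length, GC and the base composition of the region had been fitted. Sites of the words picked in 1 of 2 random parts of the genes were then tested in the other part.

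Genes were named by rule: 20 fixed genes, the 12 highest and 12 lowest genes by the interval bound nearest to equality among those with a symbol and at least 100 counts in the higher library, 4 members of each list outside the range, up to 2 members of each other list at 1.5-fold or more, and the 5 most abundant genes of each library. Some named genes and 1 gene list are not reported here. Placeholder symbols of uncharacterised loci, those that begin with LOC, were not taken as symbols. This exclusion is not part of the rule fixed beforehand and was added after the file had been opened, before ratios were computed. Other list members are named where a count is small, and these were chosen after their values were seen. Apart from it, the scaling, filters, thresholds, gene lists, naming rule and 15 alternatives were fixed before the data were examined. The alternatives covered DESeq2 1.42.0 size factors, library totals and upper-quartile factors, other filters and thresholds, a prior count of 2, a loess on mean expression, a fit on length and GC, protein-coding genes alone, and other ways to draw the random lists. A loess on transcript length, removal of read-through genes and random lists matched on transcript length (10 bins) and expression (5 bins) were added after the data were seen.

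The steps were tested on simulated data, Poisson counts drawn at the mean levels and depths of these libraries, in which 200 genes were set to differ by known folds. Of the genes set to differ 2.5-fold 98.5% were called, as were 98.5% of those set to 4-fold and 1.5% of those set to 1.5-fold. Of 13403 genes with no difference 19 were called. Intervals were checked for 13602 simulated genes, and 95.5% of them held the true ratio. The simulated counts varied by counting error alone. These shares therefore do not carry over to differences from culture, library preparation or shared reads in the measured libraries. For the lists, the measured log2 ratios were shuffled among genes within bins of expression, and 100 random lists of 25 genes were drawn. Of these lists 8.0% fell outside the range with no shift, and 84.0% fell above it when shifted by 0.5 on the log2 scale. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used, and matplotlib 3.10.9 for the plots.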

Results

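The transcriptome of A549 cells, a human lung adenocarcinoma cell line, was measured by RNA sequencing after infection with lentivirus carrying a short hairpin RNA against DEPDC1B (shDEPDC1B) or a negative control hairpin (shNC). Cells of both groups were infected with 5 µg/mL polybrene and harvested on day 2. Each group has 1 library, with 18647290 counts in shNC and 18862371 counts in shDEPDC1B, and 23607 and 23069 genes with a count. The series asks what DEPDC1B, a protein with a DEP domain, does in lung adenocarcinoma, and the comparison of the 2 libraries shows which transcripts differed when it was knocked down. There are no replicates, so no difference below has a replicate check, and what is compared is 2 libraries and not 2 conditions. All intervals in square brackets are exact 95% intervals of counting error only.

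DEPDC1B was 7.98-fold lower in the shDEPDC1B library, while its paralog DEPDC1 was at the same level in both libraries within counting error. At least 1.5-fold higher in shDEPDC1B were 15 of 37 mitotic genes, among them AURKB, PRC1 and UBE2C, 10 of 26 NRF2 target genes of the antioxidant response, such as CYP4F11 and OSGIN1, and 9 of 18 class I antigen presentation genes, and the medians of these lists lay above those of random lists. Of 22 targets and partners of the YAP and TAZ coactivators 9 were at least 1.5-fold lower, such as CRIM1 and TEAD1, though the list median lay within the range of random lists matched on transcript length (percentile 8.06) and without its farthest member (5.84). Also lower were the growth factor receptor EGFR, the actin crosslinker FLNA, the fibrillins FBN1 and FBN2, and the mitochondrial one-carbon enzymes MTHFD2 and SHMT2. Long transcripts as a class were lower and short transcripts higher, and matching on transcript length changed which gene lists lay outside the range of random lists.

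DEPDC1B (chromosome 5, 60596912 to 60700190, minus strand, GRCh38 coordinates of GENCODE 29) had 329 counts in shNC and 39 in shDEPDC1B, or 17.1 and 2.14 CPM. The log2 ratio was -2.997 [-3.51, -2.52], which leaves 12.5% [8.75, 17.5] of the shNC level. By the interval bound nearest to equality it ranked 21 among the lower of 11258 genes with at least 100 counts in the higher library, or 24 of 11471 with placeholder loci taken in. DEPDC1 (chromosome 1, 68474152 to 68497221) had 410 and 382 counts, a log2 ratio of -0.02 [-0.23, 0.18].

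Among 13850 genes with at least 30 counts in the higher library, 812 were at least 2-fold higher in shDEPDC1B and 1243 at least 2-fold lower, each with an interval that excludes equality. Lower genes made up 60.5% of these, and 71.0% (617 higher, 1514 lower) when the libraries were scaled by their totals instead of by trimmed means. The difference between the libraries was broad: the intervals of 73.8% of the genes excluded equality, and the SD of the log2 ratio across 4605 genes with at least 1000 counts was 0.70, against a median of 0.10 from the middle to the end of an interval. Counting error is therefore a small part of the differences reported for abundant genes, and the part due to culture or library preparation is unknown.

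**Figure D1:**
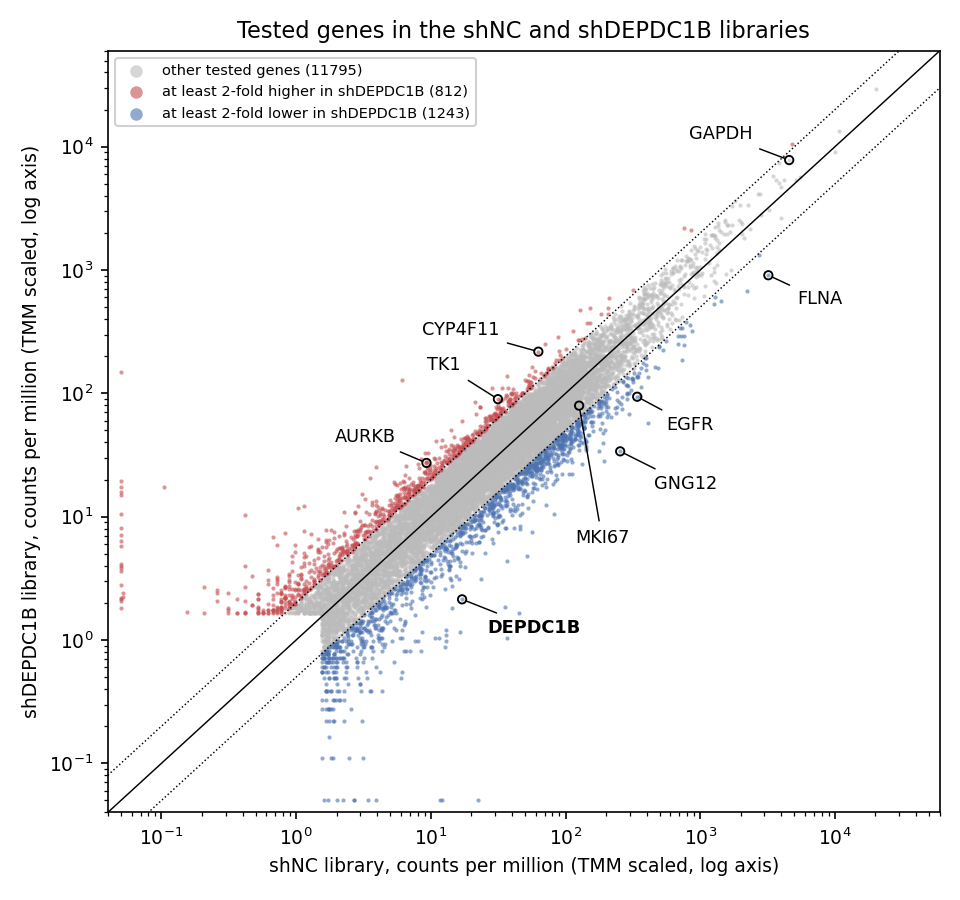
CPM in the shNC library (x axis) and the shDEPDC1B library (y axis), both on log axes, with 1 point per gene that had at least 30 counts in the higher library. The solid line marks equality and the dotted lines 2-fold differences, genes with a count of 0 in a library are drawn near its axis, and DEPDC1B lies below the lower dotted line with 17.1 and 2.14 CPM.

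The log2 ratio depended on transcript length. In the 10% of protein-coding genes with the shortest annotated transcripts (177 to 1506 nucleotides) the median log2 ratio was 0.58, and in the 10% with the longest (7647 to 109224 nucleotides) it was -0.63. Across genes, which are not independent replicates, the Spearman correlation was -0.51 with length and 0.38 with GC content, and a linear fit on both took up 24.9% of the variance. Genes at least 2-fold lower had a median transcript length of 5985 nucleotides, against 2115.5 for genes at least 2-fold higher and 3385 for all assessed genes. After this fit was subtracted, 566 of the 1110 lower genes with a known length and 328 of the 708 higher genes stayed at least 2-fold away. DEPDC1B, with a transcript of 2499 nucleotides, was at -2.91 after the fit.

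**Figure D2:**
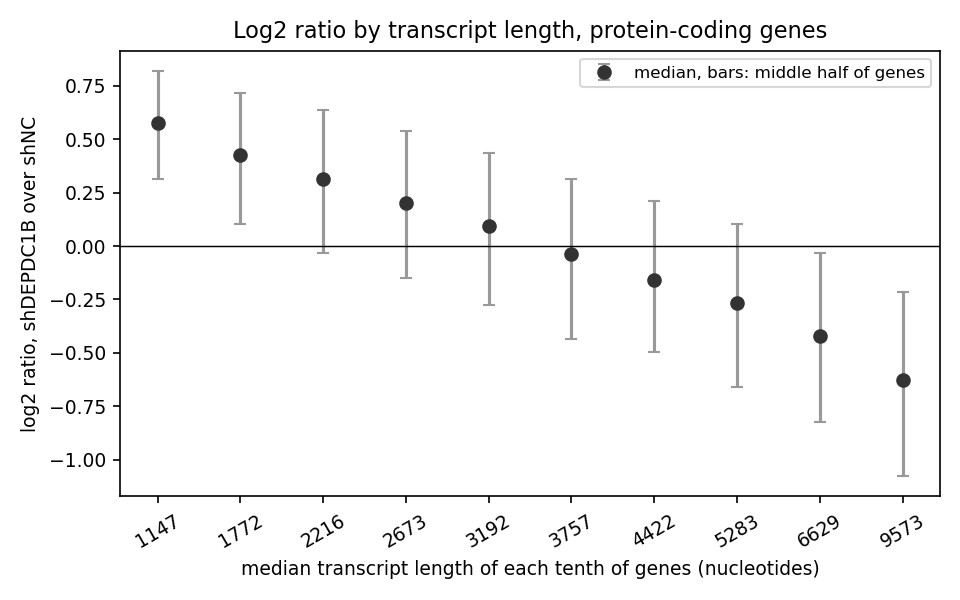
Median log2 ratio of shDEPDC1B over shNC (y axis) in 10 equal groups of protein-coding genes ordered by transcript length (x axis, median length of each group in nucleotides). Bars span the 25th to 75th percentile of genes, and the median goes from 0.58 in the shortest group to -0.63 in the longest.

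Of 38 gene lists, 33 had at least 5 assessed members, and the medians of 7 lay outside the central 95% of random lists matched on expression, where the nominal 5% of 33 is 1.65. After the ratios were shuffled within bins of expression, 8.0% of 100 random lists lay outside, too few lists to tell this from the nominal 5%. Shuffling also removes what genes of a list share, such as transcript length. The 7 lists were 6 above the range and 1 below it. When the random lists were matched on transcript length as well, 4 of the 6 stayed above (mitosis, NRF2 targets, ribosomal proteins and class I antigen presentation), and the histone, respiratory chain and YAP and TAZ lists came within the range, while the ATF4, heat shock and HEK293 and neuroendocrine lists came below it.

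Of 37 mitosis genes, 30 had a ratio above 1 and 7 below, some of them within counting error, with a median log2 ratio of 0.47 (percentile 99.97 of random lists, and 100 with length matched). At least 1.5-fold higher were 15, and those with the highest interval bounds were AURKB, a mitotic kinase, at 1.56 [1.31, 1.81], PRC1 at 1.15, KIF20A at 1.18 and UBE2C at 1.12, with CDCA8 at 1.19 [0.91, 1.46] less precisely measured. CDK1 was 0.59 [0.45, 0.72] and CCNB1 0.50 [0.41, 0.59] higher. The 4 members at least 1.5-fold lower were CENPE, CENPF, ASPM and the proliferation marker MKI67 (-0.67 [-0.76, -0.57]), and MKI67, whose transcript has 12678 nucleotides, was at -0.07 after the length and GC fit, as CENPF was at -0.02 and ASPM at 0.12, whereas CENPE went from -1.73 to -1.04. DNA replication and S phase genes had a median of 0.17 (32 genes, percentile 78.9), with CDT1, GINS2, CDC45 and TK1 (1.51) at least 1.5-fold higher and RFC3 (-1.14), CCNE2 and UHRF1 lower. Of 9 assessed replication-dependent histone genes, 5 were at least 1.5-fold higher and none lower, with a median of 0.65 (percentile 98.7). HIST1H1C was at 1.21, HIST1H2AC at 1.18, HIST1H2BK at 1.16, HIST1H2BC at 0.88 and HIST1H2BD at 0.65. The median transcript length of the list was 789 nucleotides, and the percentile among lists matched on length was 79.0.

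Of 26 NRF2 target genes, 10 were at least 1.5-fold higher and 1 lower, and 22 had a ratio above 1, with a median of 0.46 (percentile 98.8, and 98.1 with length matched). CYP4F11 was at 1.79 [1.70, 1.89], OSGIN1 at 1.45, the glutathione peroxidase GPX2 at 1.09 and AKR1C3 at 0.99, whereas the cystine transporter SLC7A11 was at -1.22 and the only member at least 1.5-fold lower. With the trend on mean expression subtracted, the list was at percentile 93.4, within the range. In the ATF4 and amino acid response list (25 genes, median -0.17, percentile 7.50, and 0.82 with length matched), the 6 members at least 1.5-fold lower were the arginine transporter SLC7A1 (-2.11 [-2.28, -1.94]), MTHFD2 (-1.91 [-2.04, -1.79]), ALDH1L2 (-1.88), SHMT2 (-1.68), SLC7A11 and SLC7A5. PCK2, DDIT3 and CEBPB were at least 1.5-fold higher, and ATF4 itself was at -0.27. Heat shock genes had a median of -0.18 (16 genes, percentile 7.96, and 0.22 with length matched), with HSP90AA1 at -1.04 and HSPH1, BAG3, HSPD1 and CHORDC1 at least 1.5-fold lower, and HSPE1 higher. Endoplasmic reticulum chaperones had a median of 0.24 (19 genes, percentile 82.1), from CRELD2 at 1.16 to SEL1L at -1.04. The 28 p53 targets had a median of 0.03 and a mean of -0.04 (percentile 45.9), but lay below the range after the length and GC fit (1.67) and after a loess on length (1.79), and within it with length matched (13.7). CDKN1A was at -0.06 [-0.10, -0.02], while EDA2R (-1.39), ZMAT3 (-1.30), SPATA18, TP53INP1 and SESN1 were lower and CCNG1, BTG2 and SESN2 higher. Apoptosis regulators had a median of -0.16 (20 genes, percentile 10.3), with PMAIP1 (-1.61), APAF1 (-1.27), BCL2L11, XIAP and BCL2L1 at least 1.5-fold lower and BID, CASP9 and BAK1 higher.

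All 27 nuclear respiratory chain genes had a ratio above 1 and 10 were at least 1.5-fold higher, with a median of 0.56 (percentile 99.99). NDUFS7 was at 1.10, COX6A1 at 0.87, SDHB at 0.81 and COX4I1 at 0.76. Their median transcript length was 1584 nucleotides, and the percentile was 93.4 among lists matched on length and 92.5 after a loess on length, within the range, but 99.9 after the length and GC fit. All 36 ribosomal protein genes had a ratio above 1 as well, with a median of 0.65, above all 10000 random lists, and 22 were at least 1.5-fold higher. RPS9 (0.93), RPL7A (0.84), RPLP0 (0.84) and RPL32 (0.83) had the highest interval bounds of this list (the RPS9 value looks like a mean over gene copies), whose median transcript length was 1170.5 nucleotides. It was at percentile 98.0 with length matched and at 58.8 after the length and GC fit. Genes of the glycolysis and hypoxia list went both ways (24 genes, median 0.10, percentile 55.7), with LDHA at 1.29 [1.26, 1.31], GAPDH at 0.77 [0.76, 0.78], ALDOA and CA9 higher and PFKFB3 (-1.05), HK2, EGLN3, PDK1 and KDM3A lower. Cholesterol synthesis genes had a median of 0.14 (24 genes, percentile 72.9), with SREBF2 at -0.98, SQLE at -0.81 and CYP51A1 lower and DHCR7 and INSIG1 higher. Fatty acid synthesis genes had a median of -0.24 (16 genes, percentile 4.79), with ELOVL5 at -0.90, FADS1 at -0.80, GPAM and ACACA at least 1.5-fold lower and AGPAT2 higher. MYC targets and ribosome biogenesis genes had a median of 0.08 and a mean of -0.11 (27 genes, percentile 56.4), with FBL higher and 6 genes lower, among them ornithine decarboxylase ODC1 (-1.68) and NOLC1 (-1.38), and MYC itself at 0.22 [0.13, 0.30].

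The YAP and TAZ list was the list below the range, with a median of -0.33 (22 genes, percentile 1.76). CRIM1 was at -2.14 [-2.23, -2.05], uncertain because its deposited value looks like a mean over gene copies, the transcription factor TEAD1 at -1.70 [-1.77, -1.63], AMOTL1 at -1.65 and ASAP1 at -0.88, and 9 members were at least 1.5-fold lower against 1 higher (NT5E). The median transcript length of the list was 4629 nucleotides. Its percentile was 8.06 with length matched and 5.84 without the member farthest from the median, both within the range. After the length and GC fit it was 0.19 and after a loess on length 0.46, both below the range. RAC1 was at 0.69 [0.64, 0.75] and the phosphatase PTPRF at -0.10 [-0.15, -0.06]. Actin cytoskeleton and SRF targets had a median of -0.05 (22 genes, percentile 13.2, 7.09 with length matched, 13.16 after a loess on length, and 0.15, below the range, after the length and GC fit), with FLNA at -1.82 [-1.85, -1.80], TAGLN at -1.23 and CALD1 lower, ACTB at 0.26 [0.24, 0.27], and TAGLN2, CFL1, MYL6 and ACTA2 at least 1.5-fold higher. Of 28 integrin and focal adhesion genes, 12 were at least 1.5-fold lower, with TNS1 (-2.04) and TNS3 (-1.63) farthest by interval bound, and CAV1, ILK, ITGB5 and ITGA5 were higher. The median was -0.15 (percentile 7.70, 70.8 with length matched, and 2.11, below the range, with the trend on mean expression subtracted), and the median length 4921.5 nucleotides. Extracellular matrix genes had a median of -0.10 (23 genes, percentile 19.6), with FBN2 at -2.78 [-2.92, -2.65] and FBN1 at -2.53 [-2.80, -2.28] among 6 members at least 1.5-fold lower, and LOXL2 (1.23), MMP14, COL6A2 and TIMP1 higher.

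Epithelial markers had a median of 0.23 (20 genes, percentile 82.8). The E-cadherin gene CDH1 was at -0.14 [-0.21, -0.06], TJP1 at -1.45 (uncertain for the same reason as CRIM1), DSP and PKP2 lower, PKP3, EPCAM and TJP3 higher, and ESRP2 had 1 and 44 counts, a log2 ratio of 5.54 [2.99, 10.9]. Mesenchymal markers had a median of -0.15 (13 genes, percentile 20.8), with ZEB1 at -1.51, FN1 at -1.08, ZEB2 and AXL lower, VIM at 0.02 [-0.02, 0.05], whose sign differed under 2 other scalings, and TGFBI and TWIST2 higher. SNAI2 had 9 and 2 counts, which allows no direction (log2 ratio -2.09 [-5.34, 0.18]). TGF-beta targets had a median of -0.05 (18 genes, percentile 30.9), with TGFBR1 at -1.05 and ID2 lower and TGFBI at 0.75, TGFB1 at 0.68 [0.59, 0.77] and LTBP3 higher. Wnt and beta-catenin targets had a median of 0.00 and a mean of -0.11 (14 genes, percentile 36.0), with TCF7 at -1.49, CTNNB1 at -0.61 [-0.66, -0.55] and NKD1 lower and NKD2 higher. The ERK feedback and immediate early genes had a median of 0.05 and a mean of -0.18 (27 genes, percentile 51.6), with EPHA4 at -3.10 [-3.98, -2.33] and SPRED2 at -1.28 among 6 lower genes and AREG, FOSB and FOS higher. EGFR had 6563 and 1714 counts, a log2 ratio of -1.86 [-1.93, -1.78] that was -1.35 after the length and GC fit.

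Class I antigen presentation genes had a median of 0.60 (18 genes, percentile 99.8, and 98.8 with length matched), and 9 of them were at least 1.5-fold higher and none lower, while 17 had a ratio above 1. PSMB10 was at 1.01, PSME2 at 0.84, B2M at 0.65 [0.56, 0.75] and CALR at 0.60. The deposited values of 10 of the 18, B2M included, look like means over gene copies, so their counts and intervals are uncertain, and genes of this list that resemble each other also share reads. Among 28 interferon-stimulated genes 10 were at least 1.5-fold higher, with USP18 at 1.87 [1.48, 2.27] and IFI6 at 1.34, and DTX3L, DDX58, TRIM22 and SAMD9 lower, for a median of 0.06 (percentile 54.6). With no filter on low counts the list had 37 genes and a median of 0.57, above the range (percentile 99.99). NF-kappaB targets had a median of -0.09 and a mean of 0.19 (21 genes, percentile 22.2), with CCL20 at 2.18 [1.53, 2.89], NFKB2 at 1.37 [1.31, 1.44], RELB, LCN2 and CCL2 at least 1.5-fold higher and TRAF1 lower. Chemokines and cytokines had a median of 0.33 (16 genes, percentile 92.0), with IL32 at 1.34, MIF, LIF, IL15, CCL20 and CCL2 higher and IL11 lower. Checkpoint ligands and immune modulators had a median of 0.10 (22 genes, percentile 62.2), with the NKG2D ligand ULBP2 at 1.84 [1.35, 2.35] and NECTIN3 at -1.67. CD274, which encodes PD-L1, had 18 and 15 counts, and a difference was not detectable at this depth (-0.18 [-1.28, 0.89]). Of the class II list only 3 genes were assessed, with RFX5 at 1.05, CTSS higher and CIITA lower (mean 0.15).

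Lung epithelial lineage genes had a median of -0.36 (11 genes, percentile 7.15), with MUC5B at -0.71 and ABCA3 at -0.66. The microRNA and short hairpin machinery had a median of -0.04 (16 genes, percentile 36.3, 96.1 with length matched, and 98.01, above the range, after the length and GC fit), with TNRC6A at -1.72, AGO1 at -1.17, AGO4, XPO5 and MAVS lower and TARBP2, AGO2 and TNRC6B higher. Markers of other cell types were mostly at or near 0 counts: 3 of 24 leukocyte genes (CD68, ITGAM and CD14, mean 0.29), 3 of 12 fibroblast genes (COL1A1, COL3A1 and ACTA2, mean 0.41) and 1 of 12 endothelial genes (EGFL7, 0.99) were assessed. The HEK293 and neuroendocrine markers had a median of -0.33 (6 genes, percentile 11.03, and 1.64 with length matched), with TUBB3 at -1.14 and INA lower and SYP higher. None of the mitochondrially encoded protein genes was among the names used here, so that list gave no value. RNR2, taken by its symbol alone as the mitochondrial 16S ribosomal RNA, was the most abundant gene in both libraries, with 389435 and 534311 counts (0.54 [0.53, 0.54]).

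**Figure D3:**
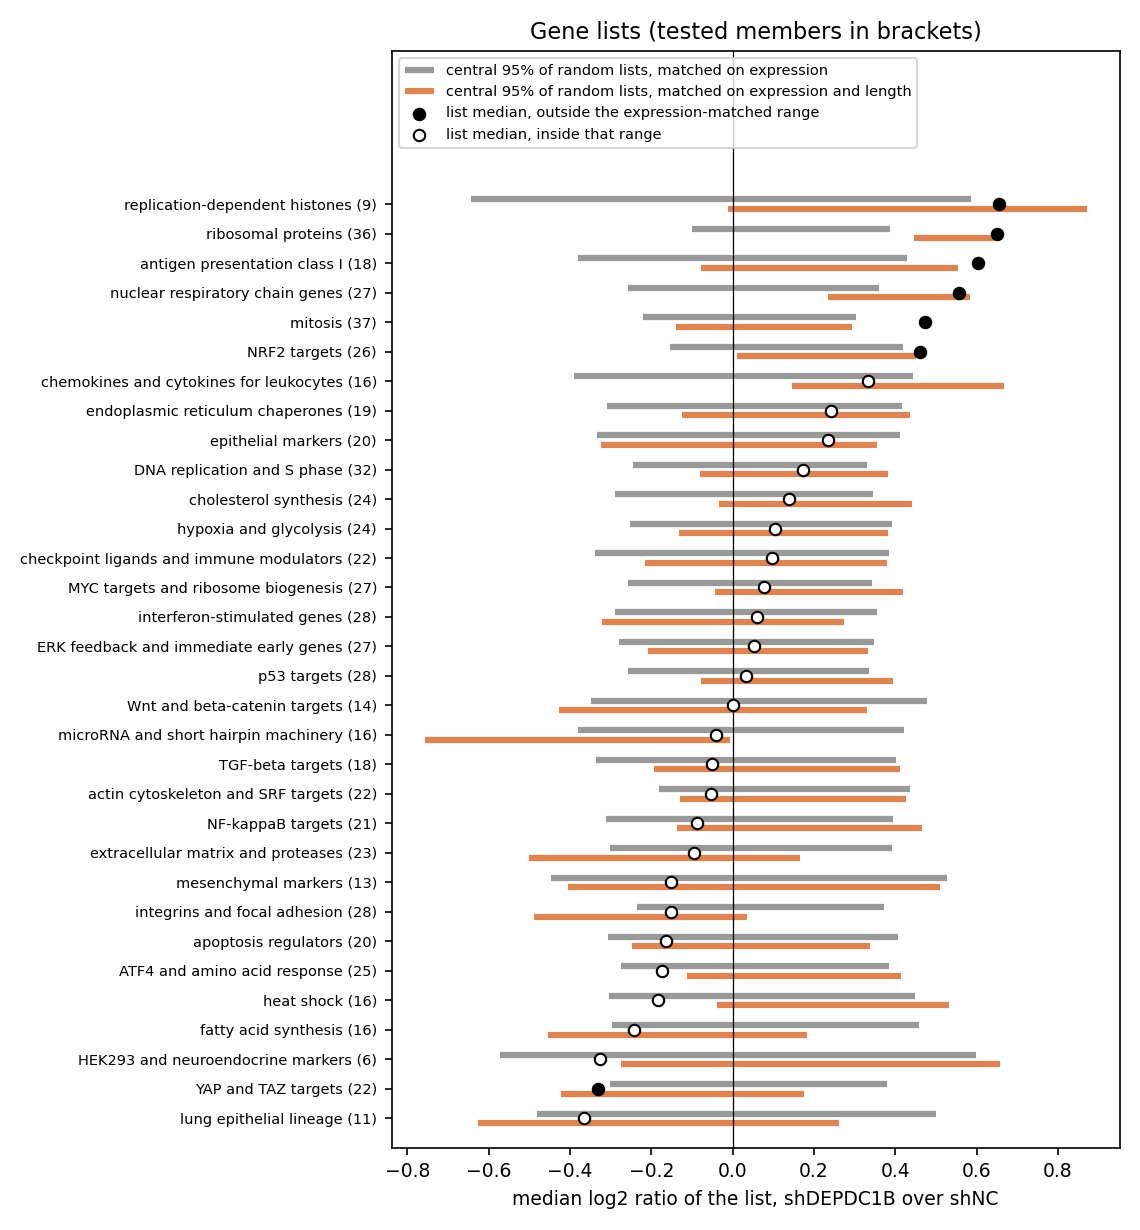
Median log2 ratio of shDEPDC1B over shNC (x axis) for the reported gene lists with at least 5 assessed genes (y axis, number of genes in brackets). Circles are list medians, grey bars the central 95% of medians of 10000 random lists matched on expression, and orange bars the same with transcript length matched too. Filled circles lie outside the grey bar, which holds for 6 lists above and 1 below.

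The other abundant genes differed little or were higher. ALDH1A1 was at -0.13, KRT8 at 0.05 and KRT18 at 0.06, with the sign of both keratins differing under scaling by library totals, EEF1A1 was at 0.32, and the ferritin light chain FTL was at 1.13 [1.12, 1.14], or 0.44 after the length and GC fit. The G protein subunit gene GNG12 had 4907 and 618 counts (-2.91 [-3.03, -2.79], and -2.55 after the fit). The annotated 3' untranslated regions of GNG12, CRIM1, TNS1 and EDA2R each hold 2 copies of the 7-base word TGGTAAC. Those of EPHA4, ZEB1, SPRED2 and TAGLN hold 1 each. This word also lies in the coding sequence of the DEPDC1B mRNA at position 1210. Of 42 named genes at least 2-fold lower with an annotated 3' untranslated region, 9 hold TGGTAAC, and 24 hold it, AGCAGCC or GCAGCCA, which also went with lower ratios. KIAA0754 is among the 9, but was matched through another symbol to a transcript of 24828 nucleotides, so its region is uncertain. Of 1006 such lower genes 21.1% hold TGGTAAC, against 13.8% [11.8, 15.8] of random genes matched on region length. TGGTAAC was picked from 15893 words because it went with the lowest ratios in these libraries, so its presence in lower genes is no separate finding.

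The 12 highest and 12 lowest genes by interval bound were mostly read-through transcripts, pseudogenes, near-identical copies or genes inside other genes, whose reads can be split in more than 1 way, so their values are uncertain. The lowest included TRIM6-TRIM34 (232 and 0 counts, at least 73.2-fold lower against a floor of 3 counts), ZBED6 (712 and 19 counts, -5.15), KIAA0754 (-4.77), NBPF10 (-4.26), RGPD6 (-3.84), ANKRD36BP1 (-3.72), PWAR5 (-3.56), NCR3LG1 (-3.46), CCDC144A (-3.44) and PFN1P2 (-3.41), beside GNG12. The highest had 0 counts in shNC for PCDHACT (at least 126-fold higher), RPL17-C18orf32 (at least 96.5-fold), LINC00294 (at least 68.0-fold), PLD4 (at least 45.4-fold), FAM72C (at least 40.9-fold) and SYS1-DBNDD2 (at least 37.3-fold), each against a floor of 3 counts. IPO11-LRRC70 had 2 and 316 counts (7.38 [5.52, 10.4]), SYNJ2BP-COX16 8 and 190 (4.65), EIF3CL 117 and 2326 (4.39), POC1B-GALNT4 20 and 213 (3.49), RAD51L3-RFFL 16 and 135 (3.16) and UPK3BL1 68 and 377 (2.55). Uncharacterised placeholder loci were left out of this ranking and would have taken 4 of the 12 highest places and 2 of the 12 lowest. The largest ratio of all belongs to LOC102723728, with 0 and 2739 counts (at least 965-fold higher), and LOC112268155 had 434 and 0 counts (at least 137-fold lower). Of 73 assessed read-through genes, 17 were at least 2-fold higher and 10 at least 2-fold lower.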

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

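The loess on transcript length, the removal of read-through genes and the random lists matched on length were chosen after the results were seen. DEPDC1B stayed lower in shDEPDC1B under all 11 alternatives that apply to it, with log2 ratios from -3.20 to -2.91. Counts of genes at least 2-fold higher and lower moved by over 1.5 times with the fit on length and GC (470 higher, 740 lower), with a ratio threshold of 1.5 (2662 higher, 2708 lower) and with the whole interval required beyond 2-fold (295 higher, 689 lower), and the loess on transcript length moved the lower count (754). A looser or stricter threshold changes the counts by construction, and for the length fits the trend they remove is measured above. Under the other settings both counts stayed within 1.5 times of 812 and 1243, and dropping the interval requirement changed neither count. Between 6 and 10 lists lay outside the range under all settings but the central 99%, which left 4 lists. Mitosis and class I antigen presentation lay above the central 95% in all 14 other settings, NRF2 targets in 13, the respiratory chain and ribosomal protein lists in 12 each, the histones in 10, and the YAP and TAZ list below it in 10. These tallies include the DESeq2, library total and upper-quartile scalings. Such scalings shift every log2 ratio alike, so the list percentiles under them equal the main ones by construction. Of 1364 values of the 128 other named genes, 49 no longer passed 2-fold, 3 newly passed it and none changed sign while called. Among the genes reported, the signs of VIM, KRT8 and KRT18 differed under another scaling. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out and no edgeR or DESeq2 test could be fitted. Depth limits genes near 30 counts, where a 2-fold ratio barely excludes equality, and genes such as CD274 and SNAI2 could not be assessed.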

Other observations

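The values in the next paragraph, the GC test and the tests on held-out genes for single seed words were chosen after the results were seen, while the other tests were set before.

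Several abundant genes outside the fixed lists had large ratios. Values after the length and GC fit are given for MALAT1 and NEAT1 only. The nuclear long noncoding RNA MALAT1 had 7862 counts in shNC and 1050 in shDEPDC1B (log2 ratio -2.83, and -2.40 after the length and GC fit), whereas NEAT1 was at -0.91 and at 0.01 after the fit. The membrane-cytoskeleton linker MSN was at -1.98, the cell cycle kinase CDK6 at -2.39, the bicarbonate transporter SLC4A7 at -2.26, the cytosolic isocitrate dehydrogenase IDH1 at -1.66 and the polyamine acetyltransferase SAT1 at -1.37. Transglutaminase TGM2 was at 1.90 [1.84, 1.97], the kinase MKNK2 at 1.84, annexin ANXA5 at 1.70 and the secreted chaperone CLU at 1.52. ELOVL7, which lies 51600 bases from DEPDC1B on the same strand, had 920 and 195 counts (-2.16 [-2.39, -1.93]).

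Long transcripts were lower in shDEPDC1B, by -0.38 on the log2 scale per doubling of length among 12288 protein-coding genes. GC content as the whole cause is argued against, since with GC in the fit the slope was -0.26 or steeper in each of 3 groups of genes by GC. The length of the 3' untranslated region alone is argued against by the slope on coding length at fixed region length, -0.22 [-0.23, -0.21], and the genomic span of the genes by its slope of -0.0292 at fixed transcript length. A difference in RNA fragment length or integrity between the libraries is a candidate explanation that cannot be told apart from an effect of the hairpin: the slope was -0.28 or steeper in each group of genes by abundance, but the slope on untranslated region length, -0.0955, did not reach the -0.10 set for it, and each group has 1 library. An effect of DEPDC1B knockdown on long transcripts stays open and untested.

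Read-through genes were common among the largest ratios. Of the 73 assessed, 37.0% differed at least 2-fold, against a median of 19.2% [10.96, 28.8] in random sets matched on abundance, with 17 higher and 10 lower. This is in line with reads shared between overlapping gene models being assigned differently in the 2 libraries, though real differences in read-through transcription were not tested.

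Genes off the length and GC fit shared words of 7 bases in their 3' untranslated regions, some of which a small RNA seed could leave, while others on the higher side, such as ACAGGCG (z 7.37), CAAGCGA (7.34) and GGATTAC (6.86), are not shifted forms of AACCAAC and overlap further such words as pieces of a longer sequence would. Among 15893 words in 12105 genes, TGGTAAC had the most negative z (-10.1) and lies in the DEPDC1B mRNA, as do 13.7% of the words searched, while AACCAAC had the largest z (10.3) and does not. A hairpin seed cannot be told apart from other sources of such words, because the condition set beforehand, a z at least 1.5 times that of any word of opposite sign, was not met but left out that the shNC library carries a hairpin of its own, and the hairpin sequences are not given in the sources used here. Another lower word, AGCAGCC (z -8.41), also lies in the DEPDC1B mRNA, as do 13.7% of the words searched. Its first 6 bases also lie reverse complemented at position 1200 of that mRNA. That is within the 21 bases that end with TGGTAAC, where 0.69% of all 7-base words have 6 bases reverse complemented. This was looked for after the words were seen, and without the hairpin sequences it cannot decide the question. Since TGGTAAC and AACCAAC were picked on these ratios, genes were split at random, each part picked its own words, and sites were tested in the other part. On the higher side ACCAACA and AACCAAC were picked, with held-out differences of 0.25 [0.15, 0.39] and 0.33 [0.26, 0.40] for 8-base sites. For AACCAAC 7-base sites were at 0.05 and 0.04, 6-base sites at 0.01 and 8-base sites in coding sequence at 0.06 [-0.03, 0.10], the order set for a seed. ACCAACA gave -0.02 and 0.12 for its 7-base sites against 0.03 for 6 bases, which is not the order set for a seed. If AACCAAC were the site, the shorter sites of ACCAACA would be out of register. However, ACCAACA also overlaps the higher word GACCAAC (z 7.06). Whether ACCAACA stems from AACCAAC or from another sequence was not tested. A seed in the shNC library stays open, because the condition asked that both parts pick AACCAAC. On the lower side GCAGCCA and TGGTAAC were picked, with 8-base sites at -0.0855 [-0.15, 0.01] and -0.17 [-0.30, -0.06], and for TGGTAAC 7-base sites at -0.13 and -0.03, 6-base sites at -0.06 and 8-base sites in coding sequence at -0.10 [-0.18, -0.02], which leaves a seed effect open as well.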
